A study of Mus musculus with 2 samples.

How the data were processed

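Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into DNA that is not packed away in chromatin, so that sites of frequent insertion mark open regions. The tissue was midbrain dissected from mouse embryos of 14.5 days, mixed sex, of a C57BL/6N background strain (B6NTac;B6NCrl/Lap). The labels give 1 group with 2 biological replicates. Replicate 1 pooled 24 embryos and replicate 2 pooled 34, and both libraries had fragments in a size range of 200 to 750 bp. No control group was given, so the comparison that the design allows is one replicate against the other, beside a description of the regions found. Replicate numbers and embryo numbers were taken from the labels.

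Peak lists deposited by the authors were used here, and they do not give the sequencing depth of each library, which is unknown. The 12 peak lists used here are on the mouse assembly mm10, per the labels. For each replicate there was a strict list thresholded on the irreproducible discovery rate (IDR) between pseudoreplicates, which are random divisions of 1 library's reads, a more lenient list of peaks found in both pseudoreplicates, and a ranked list made before any threshold. For the series there was a conservative list, thresholded on the IDR between the 2 true replicates, a strict list from pooled reads and pooled pseudoreplicates, a lenient list of peaks of pooled reads found in both true replicates (here the replicated list), a lenient pooled pseudoreplicated list, and 2 ranked lists. The texts deposited beside the lists name their output types and parents. The aligner, the peak caller, their versions and any shift of read ends to the transposase cut site are not given in the sources used here. The per-replicate lists were made by the authors from 1 replicate's reads, and the series lists from the reads of both, so a series list gives no independent value per replicate.

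Each row of a deposited peak list is 1 summit with the authors' signal value, a linear enrichment set by their peak caller against a background that is not stated. The deposited −log10 p of the row comes from the same caller. The deposited score runs from 0 to 1000. In the thresholded lists its lowest value was 540, which corresponds to an IDR of 0.05, and a score of 830 corresponds to an IDR of about 0.01. In the ranked lists the deposited score used was the −log10 of the global IDR. These peak values are the authors' and were used only to rank, filter and describe peaks within a list, or to compare regions found in both replicates.

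Rows with the same start and end were taken as 1 region, represented by its strongest summit by signal. Regions of 2 lists were called shared at an overlap of at least 1 bp. The overlap chance gives was taken from 100 seeded placements of the regions at random positions of their own chromosomes outside assembly gaps. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and counts per gene exact 95% Poisson intervals. These intervals cover counting error only. Rank agreement was given as Spearman's and Pearson's correlation across shared regions, which are not independent replicates, with a bootstrap interval from 200 draws. The replicate difference was the log2 ratio of signal values, replicate 1 over replicate 2, minus its median over shared regions, with 500 bootstrap draws for the difference between promoters and other regions.

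Annotation came from GENCODE release M21 for GRCm38, the same assembly as mm10 (chromosome lengths matched and each region of the 8 thresholded and lenient lists lay within its chromosome), and tRNA genes came from the RefSeq annotation of that assembly. A region was a promoter region where its strongest summit lay within 1 kb of a transcript start of any of the 21938 protein-coding genes, and otherwise an exon, intron or intergenic region. A gene's promoter was called open where a conservative region lay within 1 kb of any of its transcript starts. A region was called distal where no part of it lay within 1 kb of a protein-coding transcript start, and was counted for a gene within 50 kb of the gene's 5′ end. Gene lists were compared with 10000 seeded random lists of protein-coding genes of the same size, given as a percentile. For promoters the random lists were matched on 5 quintiles of the ratio of observed to expected CpG around the gene's 5′ end. CpG at a gene's other transcript starts and its number of starts were not matched. These percentiles describe these libraries. No p-value was computed, since there is 1 group and genes are not replicates. In the text a list stands above or below random lists at the 97.5th or the 2.5th percentile.

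The 19 gene lists, the 17 consensus words, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. In each list the rule named the 3 members with the strongest conservative promoter region, the 3 with the most distal regions (ties in alphabetical order), and the members without a promoter region where there were at most 5. It also named the 10 strongest distal regions, the 10 genes with the most distal regions, and the 5 shared regions with the largest replicate difference in each direction. One listed symbol, Ahsp, had no protein-coding match in the annotation. Words were searched on both strands within 75 bp of the summit of each distal region and in 2 windows of the same width centred 500 bp to either side.

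After the data were examined, further alternatives were added. They left out regions at starts of noncoding and tRNA genes, regions in which 50% or more of the 31-mers occurred more than once in the assembly, regions shared by the starts of several protein-coding genes, and shared regions without a reciprocal overlap of 50%, matched the random lists for distal regions on promoter CpG, and divided each word's ratio by the ratios of up to 40 shuffled words with the same letters. Regions were aligned to the mitochondrial genome with blastn 2.17.0 at an identity of at least 90%. The measurements were tested on simulated data with known answers: planted overlaps of 30.9% of 12407 regions were recovered as 31.4%, and 98.3% of 60 simulated lists of 15 genes raised from 60 to 95% open lay at or above the 97.5th percentile. These lists came from the middle CpG quintile, and raised lists of other sizes or CpG content were not simulated. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Regions on unplaced contigs and the mitochondrial chromosome were left out of the main measurements, which used 21 chromosomes.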

Results

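Open chromatin was mapped by ATAC-seq in the midbrain of mouse embryos of 14.5 days, in 2 libraries from separate pools of 24 embryos (replicate 1) and 34 embryos (replicate 2). The labels name no purpose beyond mapping this tissue. The data are peak lists on mm10. Their depth is unknown, and the signal values quoted are the authors' own peak values. With 1 library per replicate and 1 group, values are given per replicate without an SD, and no p-value is given.

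Replicate 1 held more open regions than replicate 2. The strict list of replicate 1 had 18469 regions covering 18.05 Mb, with a median signal of 8.10 and a median width of 976 bp. The strict list of replicate 2 had 12407 regions covering 11.5 Mb, with a median signal of 7.40 and a median width of 923 bp. The ratio of the 2 counts was 1.49, and it was 1.61 at the stricter IDR of 0.01. Most of what replicate 2 showed was also found in replicate 1. Of the replicate 2 regions, 11862 (95.6%, 95% interval 95.2 to 96.0) overlapped a replicate 1 region, against 1.41% for randomly placed regions. Of the replicate 1 regions, 11712 (63.4%, 62.7 to 64.1) overlapped a replicate 2 region, against 0.94% at random. When both lists held their 12407 strongest regions, the shares were 80.6% and 81.8%. The replicate 1 regions missing from the strict list of replicate 2 were mostly present in its lenient list, so that 90.1% (89.7 to 90.6) of all replicate 1 regions overlapped the lenient list of replicate 2. In the other direction 99.5% did.

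Regions that were strong in one replicate were strong in the other. Across the 11712 shared regions the signal values of the replicates had a Spearman correlation of 0.868 (bootstrap interval 0.862 to 0.872) and a Pearson correlation of 0.858 on the log2 scale. These are correlations across regions, which are not independent replicates. Signal was higher in replicate 1 by a median of 0.36 on the log2 scale, with an SD across regions of 0.28 around that median. Relative to the median, promoter regions were shifted toward replicate 2 against other regions (difference −0.04, interval −0.05 to −0.02, where negative means lower in replicate 1). The difference also followed base composition, with a Spearman correlation of −0.18 with GC content across regions. Regions of the lowest GC quintile (28.1 to 53.7% GC) had a median of 0.07 toward replicate 1. Regions of the highest GC quintile (65.6 to 79.4% GC) had a median of −0.07.

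**Figure D1:**
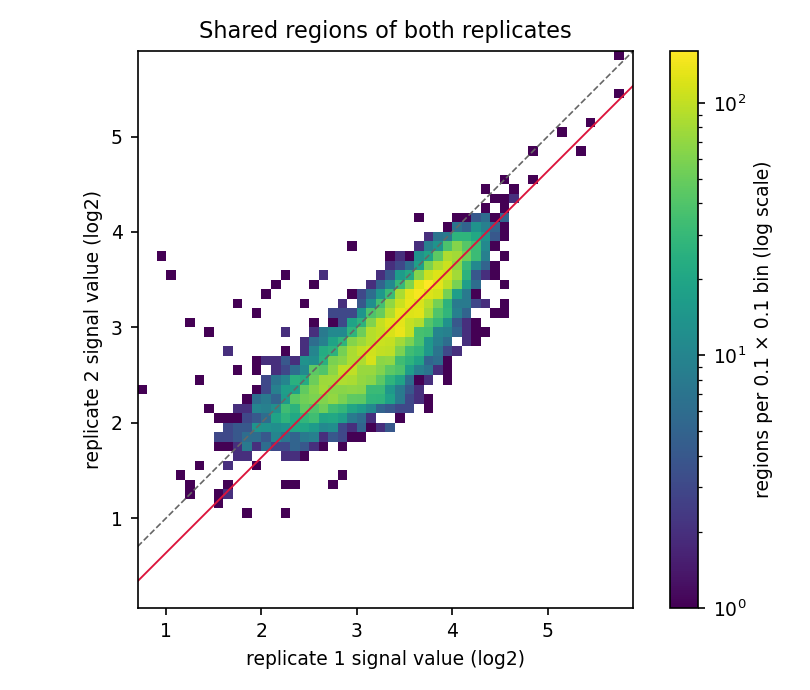
Signal values of the 11712 shared regions in replicate 1 (x axis) and replicate 2 (y axis), both on a log2 scale, with colour giving the number of regions per bin on a log scale. The dashed line marks equal values and the red line the median offset of 0.36, along which most regions lie.

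The 5 shared regions most shifted toward replicate 1 had signal values of 13.5 to 23.5 there and 4.31 to 8.61 in replicate 2. They lay in an intron of Lama3, a laminin subunit (chromosome 18, 12440042 to 12440835), in an intron of Zfp286 (chromosome 11, 62756565 to 62757404), at the start of Nmnat1, an enzyme of NAD synthesis (chromosome 4, 149485012 to 149485867), in an intron of Dnajb4, a heat shock co-chaperone (chromosome 3, 152193667 to 152194347), and 130 bp from the start of the zinc finger gene Zfp960 (chromosome 17, 17063611 to 17064314). The largest centred log2 difference among them was 1.29, at Lama3. The 5 most shifted toward replicate 2 were narrow replicate 1 regions of 150 to 385 bp set against replicate 2 regions of 917 to 1327 bp. They lay near Heatr3 (chromosome 8, 88137475 to 88137624), Pkia (chromosome 3, 7366011 to 7366183), Acyp2 (chromosome 11, 30649775 to 30649959) and Socs2 (chromosome 10, 95417527 to 95417733), and in an intron of Nav2 (chromosome 7, 48959318 to 48959702). Their centred log2 differences were −3.22, −2.90, −2.18, −1.97 and −1.95 in this order. None of these 5, and of the other 5 only those of Lama3, Dnajb4 and Zfp960, remained among the most shifted when only pairs with a reciprocal overlap of 50% were compared, an alternative added after the data were examined. The largest shift toward replicate 2 was then −1.66, in an intron of Smo (chromosome 6, 29747857 to 29748738), the Hedgehog signal transducer.

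The conservative list, thresholded between the true replicates, had 16533 regions covering 17.7 Mb. Of these, 89.9% (89.4 to 90.3) overlapped the strict list of replicate 1, 71.5% (70.8 to 72.2) that of replicate 2 and 70.0% (69.3 to 70.7) both. A further 1422 regions (8.60%) were in neither strict list. The strict pooled list had 20563 regions, 1.24 times as many, and held 95.5% (95.2 to 95.8) of the conservative regions. The lenient replicated list had 42765 regions and held 99.8% of the conservative regions, which made up 38.6% (38.1 to 39.0) of it.

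Promoters dominated the conservative list. Of its 16533 regions, 11002 (66.5%, 65.8 to 67.3) had their strongest summit within 1 kb of a protein-coding transcript start, 16.7 times the 3.98% of randomly placed regions. Introns held 1903 regions (11.5%, against 35.1% at random), intergenic sequence 3408 (20.6%, against 58.1%) and exons outside promoters 220 (1.33%, against 2.82%). Promoter regions were also stronger and wider, with a median signal of 9.43 and a median width of 1156 bp, against medians of 5.64 to 6.01 in signal and 774 to 935 bp in width for the other classes. The promoter share was 61.4% in replicate 1's own list and 76.9% in replicate 2's, and it was 35.2% in the replicated list.

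Of the 21938 protein-coding genes, 11612 (52.9%) had an open promoter. The share rose with CpG content around the gene's 5′ end, from 6.04% in the lowest quintile to 92.8% in the highest. For promoters, each gene list is therefore set against random lists matched on that CpG content. Internal transcript starts were not matched.

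Pan-neuronal genes had open promoters nearly throughout, and so did neural progenitor genes in the conservative list. Among the pan-neuronal genes, 14 of 15 were open (93.3%, 68.1 to 99.8, percentile 99.96, mean of matched lists 61.2%). The strongest was Syt1, the calcium sensor of synaptic vesicle release, with a signal of 16.9 (chromosome 10, 109010265 to 109011897; 16.3 in replicate 1 and 14.8 in replicate 2), followed by the neuronal RNA-binding protein gene Elavl4 (11.3) and the dendritic microtubule gene Map2 (10.5). The Map2 region (chromosome 1, 66386503 to 66387509) lay near an internal transcript start, far from the gene's 5′ end at 66175273. Rbfox3, a marker of mature neurons, had no conservative promoter region. Among the neural progenitor genes, 12 of 13 were open (92.3%, 63.97 to 99.8), just under the upper limit for random lists (percentile 97.46), led by Fabp7 (7.52) and Vim (7.40), both expressed in radial glia, and by Sox1 (6.67). The glutamate transporter gene Slc1a3 was the member without a conservative region, although it was open in the strict list of replicate 1 and in the replicated list. In the separate strict lists progenitor promoters were open at 11 of 13 in replicate 1 and 9 of 13 in replicate 2 (percentiles 83.9 and 60.2). They were open at 8 of 13 at the stricter IDR threshold (61.5%, percentile 30.2) and at 9 of 13 with the 5′ end of the gene alone as promoter (percentile 43.0). They passed the upper limit in the replicated list (13 of 13, percentile 98.2) and with regions at another gene's start left out (12 of 13, percentile 99.8). Of the proneural and differentiation genes, 9 of 11 were open (81.8%, 48.2 to 97.7, percentile 77.6). Btg2, an antiproliferative gene of neurogenic divisions, was strongest (11.5, chromosome 1, 134078405 to 134079611), then Hes6 (7.89) and Insm1 (5.49). Ptf1a and Atoh1, selectors of cerebellar and other neurons, had no conservative region. Ptf1a was open in the strict list of replicate 2, Atoh1 in that of replicate 1, and both in the replicated list. All 14 housekeeping promoters were open (76.8 to 100%, percentile 99.5), led by Eef1a1 (13.9), Psmb2 (13.3) and Pgk1 (13.1). The Eef1a1 region (chromosome 9, 78480839 to 78482511) lay near an internal transcript start, over 1 kb from the 5′ end at 78489151. With regions that also lie at another gene's start left out, an alternative added after the data were examined, 11 of 14 were counted (percentile 94.0). With the 5′ end of the gene alone as promoter, 12 of 14 were open (percentile 87.2). In the replicated list all 14 were, at percentile 95.3, the highest possible there.

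In the conservative list, genes of particular midbrain cell types and of the midbrain pattern were open less often than genes matched on CpG content at the 5′ end. Without the matching only the floor plate list was below random lists (percentile 1.03), while the patterning, GABAergic and glutamatergic lists were at percentiles 40.6, 21.6 and 54.4. Of the midbrain patterning genes, 9 of 18 were open (50%, 26.0 to 74.0, percentile 0.67, matched mean 73.2%). Pax5 (11.1, chromosome 4, 44703977 to 44704884) and En2 (8.01, chromosome 5, 28165077 to 28166163), both transcription factors of the midbrain-hindbrain boundary, and Spry1 (6.43), an antagonist of FGF signalling, were strongest. The Pax5 region lay near an internal transcript start, over 1 kb from the gene's 5′ end at 44710487. Of the floor plate and dopaminergic genes, 3 of 14 were open (21.4%, 4.66 to 50.8, percentile 0.07). They were Nr4a2, a regulator of dopaminergic neurons (8.005; chromosome 2, 57123370 to 57124507; 9.45 in replicate 1 and 5.14 in replicate 2), Ddc (5.05), which makes dopamine from its precursor, and Foxa1 (3.995), whose region was in neither replicate's own strict list. The Ddc region (chromosome 11, 11821491 to 11822145) lay near an internal transcript start, far from the gene's 5′ end at 11898144. With the 5′ end alone as promoter, 2 of 14 were open (14.3%, percentile 0.015). Of the GABAergic genes, 4 of 10 were open (40%, 12.2 to 73.8, percentile 1.51), with Zfpm1 (7.42), Gata3 (6.85) and Tal1 (5.52) strongest. The Gata3 region (chromosome 2, 9879320 to 9879930) lay near an internal transcript start, over 1 kb from the 5′ end at 9890034. Of the glutamatergic and motor neuron genes, 6 of 11 were open (54.5%, 23.4 to 83.3, percentile 1.97). Isl1 (9.69, chromosome 13, 116309278 to 116310275) and Pou4f1 (8.91, chromosome 14, 104467364 to 104468620), transcription factors of motor and of red nucleus neurons respectively, were strongest, followed by Neurod1 (7.40), whose region also lies at a start of Cerkl. Tfap2d, Barhl1, Phox2b, Phox2a and Slc17a6, a vesicular glutamate transporter, had no conservative region. Tfap2d and Slc17a6 were open in the strict list of replicate 1, and Tfap2d, Slc17a6 and Phox2a in the replicated list. In the lenient replicated list these 4 lists reached 77.8%, 78.6%, 90% and 81.8%, none of them below the 2.5th percentile of matched lists. In the strict list of replicate 1 the GABAergic and the glutamatergic and motor neuron lists were at percentiles 5.39 and 6.69, and in that of replicate 2 the latter was at 2.60. In the strict pooled list the floor plate, GABAergic and glutamatergic lists were at 3.56, 13.3 and 3.84, and at the stricter IDR threshold the patterning and GABAergic lists were at 4.41 and 5.73. With a promoter window of 2 kb the GABAergic and glutamatergic lists were at 6.53 and 7.55, and with the 5′ end alone the latter was at 2.79. With regions at another gene's start left out, only the floor plate list of the 4 stayed below it (percentile 1.83).

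Genes of other brain regions and tissues were mostly closed in the conservative list. No Hox promoter was open among 16, although 1 was in the strict list of replicate 1 (0%, upper limit 20.6%, percentile 0, matched mean 67.3%). Hox genes pattern the hindbrain and spinal cord. Of the forebrain transcription factors, 3 of 15 were open (20%, 4.33 to 48.1, percentile 0.005), namely Lhx2 (8.30), Dlx1 (6.74) and Emx2 (3.71), the last 2 in the strict list of replicate 1 alone. The Lhx2 region (chromosome 2, 38350810 to 38351819) lay near an internal transcript start, over 1 kb from the 5′ end at 38339281. In replicate 1's list 5 of the 15 forebrain promoters were open and in replicate 2's list 2. Of the oligodendrocyte and astrocyte genes, 1 of 12 was open (8.33%, 0.21 to 38.5, percentile 1.34), the myelin gene Mbp (4.85). In the strict list of replicate 1 there were 3 of 12 (percentile 29.5), in that of replicate 2 none, and in the strict pooled list 4 of 12 (33.3%, percentile 55.2). Of the endothelial genes, 2 of 10 were open (20%, 2.52 to 55.6, percentile 2.47), Kdr (5.04) and Erg (4.79), of which only Kdr was in a replicate's own strict list, that of replicate 1. Of the skeletal muscle genes, 1 of 10 was open (10.0%, 0.25 to 44.5, percentile 0.6), Mylpf (9.39), whose region also lies at a start of Tbc1d10b. Of the germline genes, 1 of 11 was open (9.09%, 0.23 to 41.3, percentile 0, matched mean 74.8%), Dazl (8.70; chromosome 17, 50292595 to 50293824; 10.4 in replicate 1 and 7.56 in replicate 2). Of 1135 olfactory receptor genes, 2 were open (0.18%, 0.02 to 0.64, percentile 0), Olfr94 (6.96) and Olfr658 (5.25), while the strict list of replicate 1 held none. The microglial list (0 of 11, upper limit 28.5%, percentile 8.49), the pericyte and meningeal list (2 of 10, Foxc1 at 4.84 and Twist1 at 4.20, the latter in replicate 2 alone, percentile 4.16), the erythroid list (1 of 9, Klf1 at 5.66, in replicate 1 alone, percentile 34.6) and the liver list (0 of 10, upper limit 30.8%, percentile 7.63) did not stand apart from CpG-matched genes in the conservative list. At the stricter IDR threshold the pericyte list did, with 1 of 10 (percentile 1.01). For the microglial and liver lists a count of 0 is the lowest possible, so neither could have reached the 2.5th percentile in the conservative list. With a promoter window of 500 bp the erythroid list also had 0 of 9, at percentile 8.055, the lowest possible there. In the replicated list the Hox, skeletal muscle, germline and olfactory receptor lists were still below the 2.5th percentile, at 6.25%, 20%, 27.3% and 1.06%. There 73.3% of the forebrain list and 50% of the oligodendrocyte and astrocyte, endothelial and pericyte lists were open, none of these 4 below it. With regions at another gene's start left out, the oligodendrocyte and endothelial lists were at percentiles 7.09 and 11.97, with the 5′ end alone they were at 2.79 and 4.87, and with a promoter window of 2 kb the oligodendrocyte and muscle lists were at 8.45 and 18.8.

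**Figure D2:**
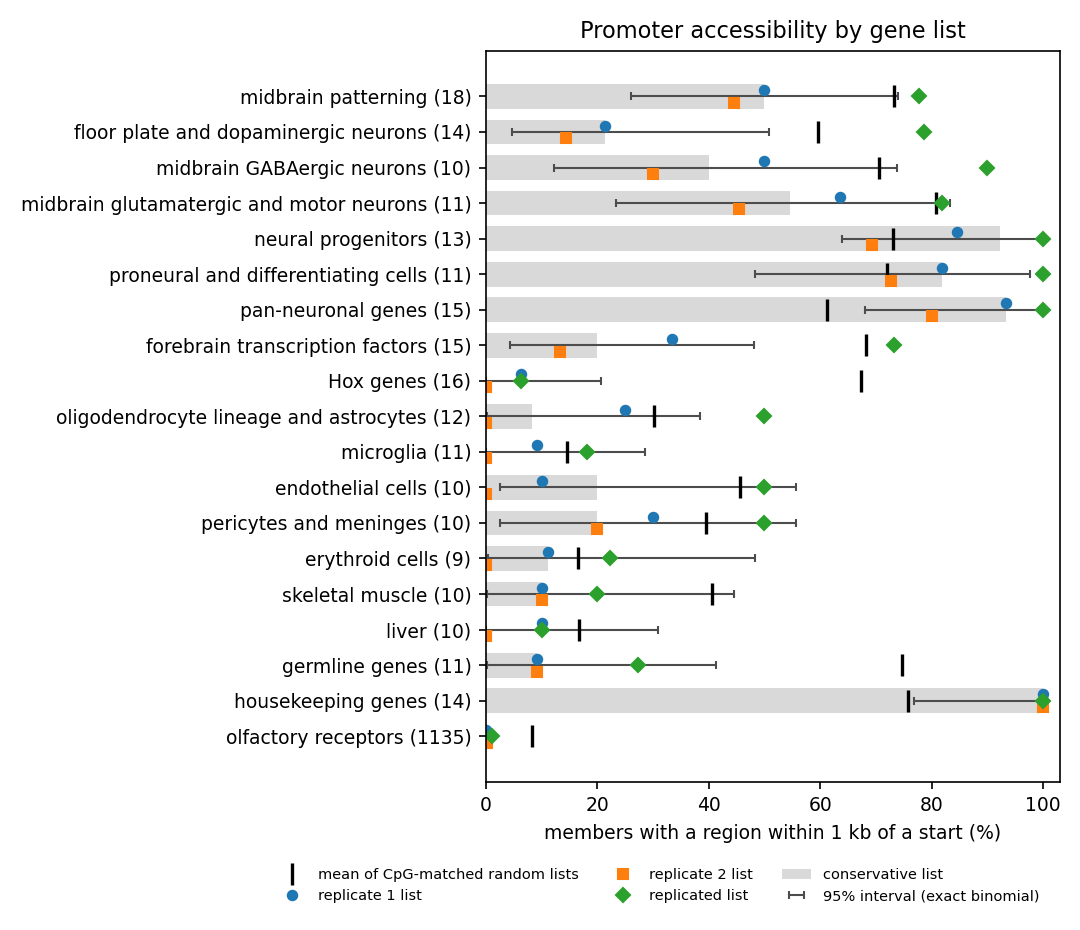
Share of each gene list's members (number in brackets) with a region within 1 kb of a transcript start, in percent. Grey bars give the conservative list with exact 95% binomial intervals, vertical ticks the mean of CpG-matched random lists, and points the strict list of each replicate and the replicated list. Pan-neuronal genes stood above their matched mean at 93.3% and Hox genes below theirs at 0%.

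Distal regions gave a different order. The conservative list held 5345 of them, a mean of 0.26 per protein-coding gene within 50 kb of the 5′ end, and 19.6% of genes had any. Percentiles of distal counts are among random lists that were not matched on promoter CpG. Midbrain patterning genes had 1.00 per gene (0.59 to 1.58, percentile 99.99), with 2 each at En2, Meis1, Meis2 and 2 further members. Midbrain GABAergic genes had 1.20 per gene (0.62 to 2.10, percentile 99.93), with 3 each at Tal1, a transcription factor gene, and at Gad2, which encodes a GABA-synthesizing enzyme, and 2 each at Gata2 and 1 other member. Proneural and differentiation genes had 1.09 per gene (0.56 to 1.91, percentile 99.8), with 4 at Btg2, 3 at Ascl1 and 2 at the Notch ligand gene Dll1. Neural progenitor genes had 0.85 per gene (0.42 to 1.51, percentile 99.5), with 3 at the intermediate filament gene Nes and 2 each at Notch1, Sox2 and 1 other member. The 16 Hox genes had no distal region (upper limit 0.23 per gene, percentile 1.52) and the olfactory receptor genes had 0.06 per gene (percentile 0). The Hox genes are neighbours in clusters on chromosomes 2, 6, 11 and 15 with overlapping windows, so they are not 16 separate counts. Neither the interval nor the random lists allow for this. In replicate 2's own list, which held 2764 distal regions against 6932 in replicate 1's, only the proneural list of these 4 stayed above the upper limit for random lists (0.82 per gene, percentile 99.8). The patterning, GABAergic and progenitor lists had 0.33, 0.50 and 0.38 per gene there, at percentiles 93.1, 97.1 and 94.3. In replicate 1's own list all 4 were above it. The Hox list, with no distal region in either replicate, was at percentile 6.37 in replicate 2's list, the lowest possible there for a list of its size.

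The other lists lay between these limits in the conservative list. Floor plate and dopaminergic genes had 0.21 per gene (percentile 44.4; 2 at Ddc, 1 at Msx1). Glutamatergic and motor neuron genes had 0.27 (percentile 58.3; 2 at Slc17a6, 1 at Pou4f1). Pan-neuronal genes had 0.40 (percentile 81.3; 3 at the synaptic gene Snap25, 1 each at Dcx, Stmn2 and 1 other). Forebrain transcription factors had 0.40 (percentile 81.9; 2 each at Foxg1 and Tbr1, 1 at Lhx6). The oligodendrocyte and astrocyte list had 0.50 (percentile 89.3; 2 each at Sox10 and Cspg4, 1 at Aqp4). Skeletal muscle genes had 0.60 (percentile 93.9; 2 each at Acta1 and Ckm, 1 at Myh3). Housekeeping genes had 0.64 (percentile 97.2; 4 at Ubc, 2 at Eef1a1, 1 at Actb). The pericyte and meningeal list had 0.40 (percentile 79.2; 2 at Pdgfrb, 1 each at Col1a1 and Foxc1). Liver genes had 0.40 (percentile 78.3; 1 each at Apoa1, Apoa2, Fgb and 1 other). Germline genes had 0.36 (percentile 74.7; 2 at Mael, 1 each at Sycp1 and Sycp3). Erythroid genes had 0.11 (percentile 26.6; 1 at Klf1), microglial genes 0.09 (percentile 18.6; 1 at Csf1r) and endothelial genes 0 (upper limit 0.37, percentile 5.70). The endothelial value is the lowest possible, so that list could not have fallen below the lower limit for random lists. Some of these lists stood above random lists under other settings. Housekeeping genes did in the strict lists of replicates 1 and 2 (percentiles 99.2 and 98.2) and, with skeletal muscle genes, in a window of 100 kb (98.4 and 98.1). With noncoding and tRNA starts left out, an alternative added after the data were examined, housekeeping genes had 0.29 per gene (percentile 72.5). In the replicated list the glutamatergic and motor neuron, oligodendrocyte and astrocyte, microglial and forebrain lists did, at 2.91, 2.75, 2.73 and 2.07 per gene (percentiles 99.7, 99.8, 99.7 and 98.1), against a mean of 1.11 over all genes. Of the microglial total of 30, C1qb, C1qc and C1qa gave 6, 5 and 5. They are neighbours on chromosome 4 with overlapping windows, so a region there can count for several of them. The random lists were not matched on such clustering. Among the olfactory receptors, Olfr1423 had 4, and Olfr1368 and Olfr263 had 3 each.

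**Figure D3:**
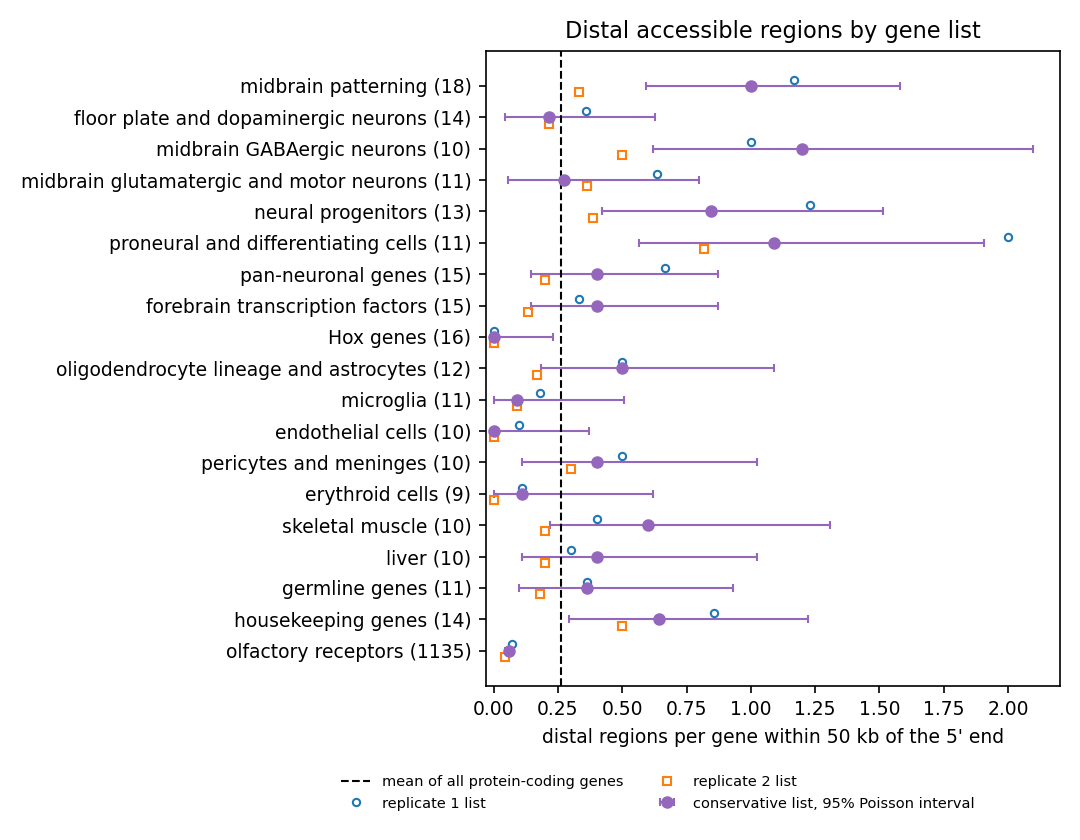
Mean number of distal regions per gene within 50 kb of the 5′ end for each gene list (number of members in brackets). Filled points give the conservative list with exact 95% Poisson intervals, open circles and squares the strict lists of replicate 1 and replicate 2, and the dashed line the mean of 0.26 over all protein-coding genes. Midbrain GABAergic genes had 1.20 per gene in the conservative list and 0.50 in the list of replicate 2.

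The strongest single distal region was intergenic on chromosome X (143482934 to 143483181), 35531 bp from the 5′ end of Pak3, a kinase of neuronal development, with a signal of 57.4 (55.4 in replicate 1 and 55.9 in replicate 2). The next were intergenic on chromosome 2 (69355469 to 69355735, nearest gene Abcb11) at 52.7, chromosome 10 (96077546 to 96077951, Gm5426) at 41.4, chromosome 2 (3964418 to 3964690, Frmd4a) at 38.6, chromosome 5 (60042765 to 60043146, G6pd2) at 36.6, chromosome 12 (97061368 to 97061856, Galc) at 28.9, chromosome 4 (80002694 to 80003057, Tyrp1) at 26.9, chromosome 16 (17222196 to 17222580, Hic2) at 25.1, chromosome 8 (19784432 to 19785057, 4930467E23Rik) at 24.7, and in an intron of Cldn34d on chromosome X (76598492 to 76599194) at 24.2. The nearest 5′ end was 3917 to 1765838 bp away. All 10 were in both replicates' strict lists. Those on chromosomes 10, 5, 12 and 4 aligned to the mitochondrial genome over 86.7%, 87.7%, 74.6% and 99.7% of their length, at 95.04 to 99.7% identity, and the one nearest Abcb11 over 48.3%.

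By number of distal regions within 50 kb, the first genes were Gm21860 on chromosome Y with 9, then Abt1, Btn1a1 and Fcgr3 with 8 each, Btn2a2 with 7, and BC107364, Eapp, Gm21887, Klrb1c and Nr2f1 with 6 each. Abt1, Btn1a1 and Btn2a2 are neighbours on chromosome 13 and share regions. All their distal regions, and 7 of those at Fcgr3, lay within 1 kb of a tRNA gene, and all 6 at BC107364 and at Eapp within 1 kb of a noncoding or tRNA start. At Eapp and Gm21887 all 6 regions, and at Gm21860 7 of 9, were mostly sequence found more than once in the assembly. Nr2f1, a nuclear receptor of brain patterning (5′ end at 78199757 on chromosome 13), had 6 regions of which none was near a noncoding start or mostly repeated, although the strict lists of replicates 1 and 2 held only 3 and 2.

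Consensus words of several transcription factor families were concentrated at the summits of the 5345 distal regions. Of the 17 words, 10 were more frequent at the summit than in the flanks by intervals that did not overlap. The word of CTCF, the insulator protein of chromatin loops, lay within 75 bp of the summit in 5.97% of distal regions (5.35 to 6.64) and in 0.13% of flanking windows, a ratio of 45.6 (26.7 to 77.7). The RFX word, bound by regulators of ciliary genes among others, had a ratio of 11.6 (8.98 to 14.9; 7.46% of summits) and the NFI word, of factors of glial and neuronal differentiation, 7.82 (4.04 to 15.1). The POU octamer had a ratio of 3.40 (2.68 to 4.33), the E-box CAGCTG 2.63 (2.41 to 2.87), the proneural E-box CAGATGG 1.89 (1.63 to 2.18) and the SOX word 1.81 (1.62 to 2.03). The GC-rich words of NRF1, ETS and SP/KLF factors had ratios of 13 (2.93 to 57.6), 6.33 (3.31 to 12.1) and 4.52 (4.05 to 5.04). The NRF1 ratio rested on 13 summit and 2 flanking windows, and shuffled words with the letters of the SP/KLF word had a median ratio of 3.79. Shuffled words of CAGCTG and CAGATGG had medians of 1.51 and 1.19 and reached 2.30 and 1.79, none as high as the word. Those of the SOX word and the POU octamer had medians of 0.79 and 0.48. Of the 40 shuffled words each for NFI and ETS, 1 was as high as the word (8.4 and 6.57). In the list of replicate 2 the ratio was 21.6 (10.9 to 42.6) for CTCF, 4 (1.71 to 9.33) for NFI and 14 (4.92 to 39.9) for ETS, and in that of replicate 1 it was 3.83 for ETS and 26 for NRF1. In the replicated list it was 26.9 for CTCF, 5.64 for RFX, 1.89 for the POU octamer and 1.93 for ETS, and each of these words was more frequent at the summit there and in both replicates. The ratios of the LIM-homeobox word (2.25, 1.30 to 3.90), AP-1 (1.13, 0.92 to 1.40), OTX (0.95, 0.82 to 1.09), TEAD (0.94, 0.84 to 1.05), homeodomain (0.87, 0.74 to 1.01) and MEF2 (0.40, 0.18 to 0.90) words rested on overlapping shares. The homeodomain word was less frequent at summits than in flanks in the lists of replicates 1 and 2 (0.82 and 0.69), although shuffled words with its letters had a lower median ratio of 0.35 in the conservative list and none was as high as the word. The LIM-homeobox word had a ratio of 1.06 in the list of replicate 2, and it was more frequent at summits in the replicated list (1.93), with windows of 50 bp (2.92) and with flanks 1 kb away (3). None of its 40 shuffled words was as high. The GATA word was less frequent at summits (4.17%) than in flanks (8.40%), a ratio of 0.50 (0.43 to 0.57). Summit windows held 56.0% GC and flanks 45.9%, and shuffled words with the letters of the GATA word had a median ratio of 0.41, below that of the word itself.

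The words of promoter regions differed in part from those of distal regions. In the 11188 conservative regions that reached within 1 kb of a protein-coding start, the SP/KLF word was at 60.05% of summits against 15.9% of flanks, the ETS word at 6.68% against 0.36% (ratio 18.7, 14.8 to 23.5) and the NRF1 word at 1.47% against 0.06% (ratio 23.4, 13.6 to 40.4). The CTCF word was at 0.78% of promoter summits, against 0.098% of their flanks (ratio 7.91, 4.96 to 12.6) and 5.97% of distal summits. The RFX word (ratio 4.90, 3.99 to 6.01), the POU octamer (1.63, 1.25 to 2.12) and CAGCTG (1.26, 1.16 to 1.36) were also more frequent at promoter summits than in their flanks. The homeodomain (0.16), GATA (0.23), OTX (0.35), proneural E-box (0.63), TEAD (0.65), AP-1 (0.67) and SOX (0.79) words were less frequent at promoter summits than in their flanks. Promoter summit windows held 66.8% GC against 53.3% in their flanks, and no shuffled words were run for promoters.

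**Figure D4:**
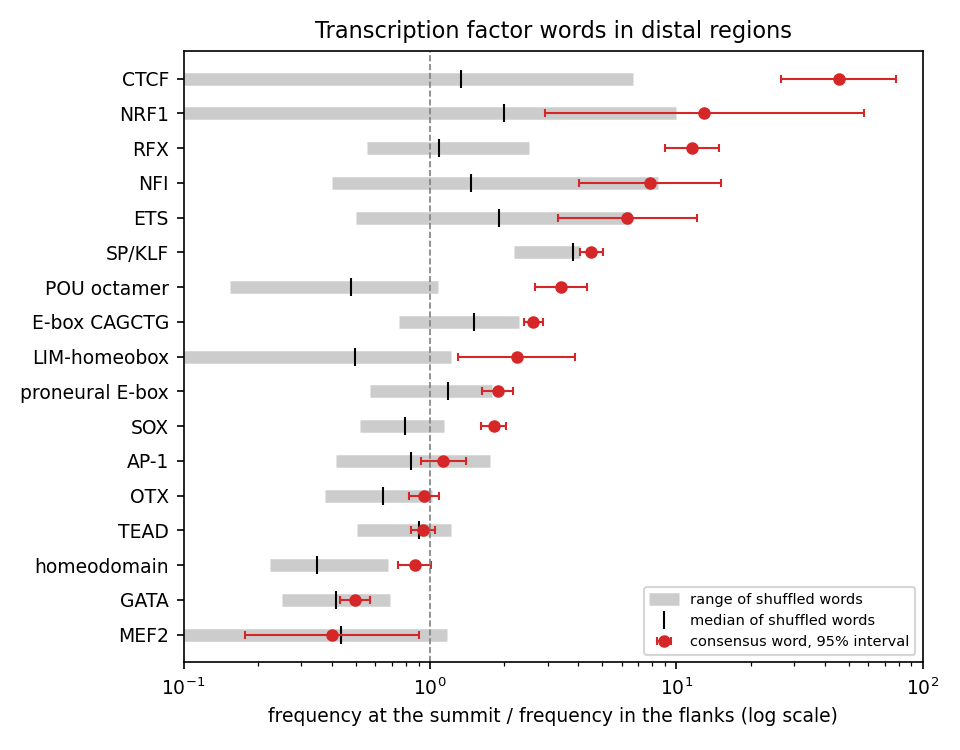
Frequency of each consensus word within 75 bp of the summit of distal regions divided by its frequency in flanking windows, on a log axis. Red points give the word with its 95% interval, grey bars the range of shuffled words with the same letters (drawn from 0.1 where it reaches lower) and ticks their median. CTCF at 45.6 lies beyond its shuffled words, and GATA at 0.50 lies within the range of its own.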

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

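The tests of which regions the thresholded lists leave out, with their signal, position and mitochondrial alignment, were chosen after the ranked lists were seen. In the ranked lists, which the comparisons of the report do not use, some regions passed the IDR threshold of 0.05 and were still left out of the thresholded list made from them. On the chromosomes there were 60 such regions for replicate 1, 64 for replicate 2, 63 for the conservative list and 80 for the pooled strict list. These counts exceed the 3 that a count of 0 allows, a low limit that a filter removing a few regions would also pass. On unplaced contigs, which the thresholded lists leave out altogether, 78, 124, 85 and 148 summits passed the threshold in the same order. No left-out summit lay on the mitochondrial chromosome. The 63 regions left out of the conservative list had a median signal of 8.27 against 7.88 in the list itself, and 16 of them exceeded the 90th percentile of conservative signal. The highest reached 49.6 (chromosome 9, 24541939 to 24542232). At promoters lay 18 of the 63, and 1 of them aligned to the mitochondrial genome over 50% or more of its length. The sources used here do not say why these regions were left out. A filter of regions is possible but could not be checked.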

How the results depend on the processing

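Replicate 1 held more regions than replicate 2 under each threshold and way of counting run. The promoter shift toward replicate 2 stayed negative under the 3 alternatives run for it. It was −0.04 on the log2 scale both in the lenient lists and with reciprocal pairs. With ranks in place of log2 values it was −0.015, on a scale of ranks that cannot be set beside the log2 values. Depth is unknown, and the values of lists rest on the authors' thresholds. No paired analysis was possible because the labels give 1 group. Where a value moved, the cause was not tested. The alternatives on reciprocal pairs, repeated sequence, noncoding and tRNA starts, shared starts, shuffled words and CpG-matched lists for distal regions were chosen after the data were examined. With windows of 50 bp the NRF1 word had no flanking match and gave no ratio.

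Counting every summit gave 47401 and 31219 for replicates 1 and 2, and the lenient pseudoreplicated lists gave 49459 and 32925. The share of replicate 1 regions found in replicate 2 was 60.02% with 50% of the region covered, and the shares in each direction were 59.4% and 88.4% with reciprocal overlap, 56.99% and 84.8% with summits within 100 bp, 48.4% and 75.9% in the lenient lists, 61.0% and 98.7% at the stricter threshold, and 80.6% and 81.8% at equal length. The rank correlation was 0.858 in the lenient lists, 0.846 at the stricter threshold and 0.913 for −log10 p. The promoter share of regions was 57.7% in the pooled strict list, 35.2% in the replicated list, 77.2% at the stricter threshold, 63.8% and 68.7% with promoter windows of 500 bp and 2 kb, and 61.4 to 76.9% without either replicate.

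Lists below random lists in promoters numbered 11, and 7 in the pooled strict list, 4 in the replicated list, 7 with a window of 2 kb and 6 with regions at another gene's start left out. Without either replicate they numbered 8 to 10. Lists above numbered 2, and 1 with the gene's 5′ end only. Lists above in distal regions numbered 4, and 8 in the replicated list and 2 to 5 without either replicate. Lists below numbered 2, and 1 with a window of 25 kb and 1 to 2 without either replicate. Words less frequent at the summit numbered 1, and 2 in the replicated list and without either replicate, and 0 against shuffled words. There 15 words had intervals above the median of their shuffled words, although for 7 of the 17 words some shuffled word was as high, GATA with 9 of 29 and NFI and ETS with 1 of 40 each among them. Among single gene lists, the replicated list moved 9 of 19 promoter shares and 17 of 19 distal means beyond their intervals, all upward, and replicate 2's own list moved 3 and 8, all downward.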

Other observations

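The families in this paragraph were chosen after the data were examined, and their percentiles are among CpG-matched random lists. Across all 39 Hox genes, 1 promoter was open in the conservative list (2.56%, interval 0.06 to 13.5, matched mean 70.5%). Clustered protocadherins, adhesion genes of which single neurons use few, had 2 open promoters of 55 (3.64%, 0.44 to 12.5, matched mean 58.8%, percentile 0). Keratin genes had 0 of 49 (upper limit 7.25%) and vomeronasal receptor genes 1 of 327 (0.31%). Zfp zinc finger genes stood on the other side with 294 of 365 (80.5%, 76.1 to 84.5, matched mean 61.3%, percentile 100). Semaphorin and plexin genes of axon guidance had 24 of 29 (82.8%, 64.2 to 94.2, percentile 99.5), and GABA-A receptor genes 9 of 13 (69.2%, 38.6 to 90.9, percentile 97.7). Ribosomal protein genes (74 of 79, percentile 99.98) and proteasome genes (35 of 39, percentile 99.8) stood on that side too. Other neuronal families did not in the conservative list: ephrin and Eph genes had 17 of 22 (percentile 51.5), glutamate receptor genes 16 of 28 (percentile 30.0) and Kcn potassium channel genes 41 of 94 (percentile 0.53). Sox genes, a family not restricted to neurons, had 11 of 19 there (percentile 0.78). In the replicated list ephrin and Eph genes had 22 of 22 (percentile 97.99), glutamate receptor genes 23 of 28 (percentile 90.3), Kcn genes 64 of 94 (percentile 67.0) and Sox genes 15 of 19 (percentile 4.66). Fox genes had 20 of 44 (45.5%, 30.4 to 61.2, percentile 0.01) and interleukin and chemokine genes 13 of 117 (11.1%, 6.05 to 18.3, percentile 0).

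Noncoding genes were open at differing rates. Of 403 tRNA genes, 170 had a conservative region within 1 kb (42.2%, 37.3 to 47.2), and of 10150 long noncoding genes 1803 did (17.8%, 17.0 to 18.5). Of the 7796 long noncoding genes over 2 kb from protein-coding starts, a filter not applied to the tRNA genes, 454 did (5.82%, 5.31 to 6.37). Distal regions with the RFX word had a median signal of 6.50 against 5.85 for those without it, and those with the SP/KLF word 6.45 against 5.79, whereas those with the CTCF word had 5.68 against 5.92. The conservative promoter regions of Foxa1, Lhx5, Notch1, Pax6, Erg and Gap43, named after their values were seen, had no signal in either replicate's own strict list, although Gap43 had another promoter region in both. The strongest promoter region lay 122 bp from the 5′ end of Cdc25c, a phosphatase of mitotic entry (chromosome 18, 34751426 to 34752143), at a signal of 24.1.

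In the 3 patterns that follow, the tests of regions open only in replicate 1, of all distal regions that align to mitochondrial DNA and of the 5 regions without such an alignment were chosen after the results were seen. The design gives 1 group, so for the first 2 patterns no biological explanation was tested.

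The first pattern is the strength of the leading distal regions, which exceeded every promoter region. Reads of mitochondrial DNA placed on nuclear copies of it are a candidate explanation for 4 of the 10, which align to the mitochondrial genome over 50% or more of their length, as do 8 of the other 5335 distal regions. For the set of 10 as a whole the count (12.2 to 73.8% by its interval) decided nothing, and of all 12 aligned regions 50% (21.1 to 78.9) were in the strongest 10% by signal. For the 5 regions on chromosomes X (both), 2 near Frmd4a, 16 and 8, no alignment was found at the identity required here (0%). These 5 were picked for having none, so the 0% was fixed by the choice and decided nothing about the explanation. Sequence in several copies stays open, since the median share of 31-mers found more than once was 29.1% over the 10 regions (6.91 to 77.9%), against a median of 0% over all distal regions.

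The second pattern is the crowding of distal regions near 10 genes. Starts of noncoding genes counted as distal may account for a large part, because 31 of the 58 regions (53.4%, 39.9 to 66.7) lay within 1 kb of a noncoding or tRNA start, against 11.2% (10.3 to 12.04) of the other distal regions. Sequence in several copies stays open, with a median of 20.1% of 31-mers repeated (14.1 to 51.7), and it was uneven, at 98.3% and 100% for Eapp and Gm21887 and 5.54% for Abt1. With noncoding and tRNA starts left out, Gm21860, Klrb1c and Nr2f1 led with 9, 6 and 6 regions, and with repeated sequence left out Abt1 and Btn1a1 still had 8, Btn2a2 and Fcgr3 7 and Nr2f1 6.

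The third pattern is the larger number of regions in replicate 1. A lower depth or enrichment in replicate 2 is a candidate explanation, since 87.1% (86.2 to 87.8) of the 6757 replicate 1 regions missing from the replicate 2 list were in the weaker part of the replicate 1 list, below its median signal. Regions open only in the embryo pool of replicate 1 stay open as an explanation for 27.0% (25.9 to 28.04) of the missing regions, which were absent from the lenient list of replicate 2 too, and 94.6% of these were below the median signal. The other 73.0% (72.0 to 74.1) were in that lenient list. Depth, enrichment and a lower accessibility in the second pool were not tested apart, since read counts were not analysed here.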
